A study of Homo sapiens with 90 samples.

How the data were processed

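The 90 samples of the series came from the NCI-H1299 line and were grouped by the labels' treatment and assay. CAGE had 2 libraries for each of DMSO, DAC, SB939, SAHA and DAC+SB939, bisulfite sequencing had 1 library for each of DMSO, DAC, SB939 and DAC+SB939, and 76 chromatin immunoprecipitation samples were not analysed here. Per the labels' protocols, RNA was extracted with RNeasy columns and CAGE libraries were made with a commercial CAGE kit, and DNA was extracted with DNeasy columns, converted with an EpiTect kit and sequenced from PCR-free libraries. The submitters' processing notes name HISAT 0.1.6, BWA, MACS2 and the build hg19, with no role for each. Which tool clustered and normalized the CAGE tags is not given in the sources used here.

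For CAGE, the authors deposited one table of 76581 consensus clusters with a mean per treatment, a normalized tag signal averaged over both libraries. The column totals were 12000186 in DMSO, 11636607 in DAC, 11542573 in SB939, 12273061 in SAHA and 14065194 in DAC+SB939. Every value was divided by 12.3, the mean of the 5 totals in units of 1e6, to give TPM on a common scale, so the authors' relative scaling of the treatments was kept. No column of another sample was used. For bisulfite sequencing, the authors deposited, per the file headers, the count of methylated calls and the count of all calls at each of 28162537 CpGs, with 2 lanes merged and both strands in 1 position. The same files hold a methylation fraction smoothed by the authors with BSmooth, per the file headers, which was used only as an alternative. Positions matched the cytosines of CpGs in GRCh37 when counted from 0 and are printed from 1.

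The written design had assumed tag counts per library. The table held treatment means instead, so the main result for CAGE is a rule of size without a test, as the design provides for that case. A cluster counted as changed when log2 of the values with a pseudocount of 1 TPM differed by 2-fold or 4-fold and the higher value reached 1 TPM. A fold on this scale understates the change of weakly expressed clusters. No fold of a single cluster is given against DMSO where it is listed at 0 there; medians over lists and families include such clusters at the pseudocount. The interaction of the combination was the log2 change of DAC+SB939 minus the changes of DAC and SB939, all against DMSO.

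After the data were seen, the libraries behind each mean were recovered. Each mean is the sum of 2 whole numbers times 2 fixed steps, 1 step per library, and a search up to 9999 normalized tags found a unique pair for 100% of the values below that limit, or 99.8% of all values. After a random shift at most 0.1% of values could be solved, and 20000 simulated values were all recovered correctly. The whole numbers skip some low values in some libraries, so they are not raw reads in all of them, and no count model was used. The labels call 1 CAGE library of each treatment paired-end and the other single-end, but the steps carry no label, so the libraries are named deeper and shallower by their step. Recovered values were tested on log2(TPM + 1) with limma-trend (limma 3.58.1 in R 4.3.3) over 32321 clusters and all 10 libraries, with 5 residual and 3.24 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A cluster was included if it held at least 1 TPM in 2 or more of these libraries. A start site silent in DMSO was thus tested only where a treatment raised it, which favours rises among tested list members. This test was added after the data were seen. It was tested on simulated libraries with 200 changed clusters, and the share recovered for DAC against DMSO stands in the report.

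Clusters were annotated with GENCODE v44 lifted to GRCh37. A cluster was assigned to a gene when it lay within 500 bp of an annotated start on the same strand, which held for 35003 clusters (45.7%), and otherwise called exon, intron, antisense or intergenic. The first base of a cluster fitted the pyrimidine-purine pattern of start sites in 33.9% of 4000 clusters, against 13.3% and 14.7% 1 bp to either side. A gene's main cluster was the assigned cluster with the highest mean. Genes were named by a rule written before the data were examined. For each comparison with DMSO it takes the 10 largest rises and 10 largest falls past 4-fold with the higher value at 5 TPM or more, a mean of at least 2 TPM, both libraries of the treatment beyond both DMSO libraries and a gene symbol, 1 cluster per gene. That cluster is the highest among those of the gene that passed, and need not be its main cluster. It adds the 5 clusters without an annotated start that rose most, up to 4 members per list, and DAPK1, CDKN1A, DNMT1, UHRF1 and TP63.

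Fixed before the data were examined were 22 gene lists with 434 entries, of which 432 matched a gene symbol. They cover cancer-testis antigens, interferon response, antigen presentation, genes reported to answer deacetylase inhibitors, metallothioneins, replication-dependent histones, proliferation, the epigenetic machinery, neuronal genes, genes reported to start in LTR12 repeats, genes silenced by methylation in tumours, p53 targets, ATF4 stress, cholesterol synthesis, epithelial-mesenchymal genes, imprinted genes and control genes. Markers of leukocytes, fibroblasts, endothelium, lung epithelium and trophoblast complete them. A list's median change was set against 10000 random lists of the same size matched on mean expression, and lists were tested among 14621 genes with camera at a preset correlation of 0.01 and again with the correlation estimated. Metallothioneins, histones and cancer-testis antigens have near-identical copies that can share reads, so values of single members are uncertain.

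Families of induced start sites were built from sequence alone. Sequences from 250 bp before to 100 bp after the centre of each cluster past 4-fold upward in the combination were aligned to each other. BLAST+ 2.17.0 was used (at least 150 bp aligned, E-value of 1e-10 or less). Clusters linked by such alignments, directly or through other clusters, formed a family, which gave 31 families of 3 or more clusters. The seed of a family was the member with the most matches. The seeds of the largest families were aligned to the genome in the same way, and a cluster within 100 bp of a copy's matching start position on the same strand was given to that copy. No repeat annotation was used here.

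Methylation levels are methylated calls as a percentage of all calls at CpGs with at least 5 calls in all 4 libraries, pooled over a class or averaged over windows of 500 bp to each side of a cluster with at least 3 CpGs, and 250 bp for family copies. Total calls were 458, 401, 429 and 412 in units of 1e6 for DMSO, DAC, SB939 and DAC+SB939. Intervals of methylation levels are 95% Wilson intervals, and they and the p-values of Fisher's exact test cover counting error only. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, numba 0.67.0, networkx 3.6.1 and matplotlib 3.10.9.

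Alternatives covered the pseudocount, the filter on low values, median centring, quantile normalization, single libraries, leaving out each library, the coverage minimum, the window, pooled levels and the smoothed fraction. Median centring, written below as the median of all clusters set to 0, subtracted the median log2 level of each treatment or library. It does not set the median change from DMSO to 0. For clusters counted by size that median went from 0.02 to -0.10 in DAC and from 0.11 to -0.14 in SB939. It went from 0.01 to -0.09 in SAHA and from 0.31 to -0.29 in the combination. The test on recovered libraries, the deeper and the shallower libraries alone, voom weights and depth order as a block were added after the data were seen. The concordance of SB939 and SAHA was set against 20 simulations of unchanged groups with shared DMSO libraries.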

Results

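The series examined which transcription start sites a human lung cancer line uses after its DNA methylation or its histone deacetylases are inhibited. NCI-H1299, a p53-null non-small-cell lung carcinoma line carrying an EGFP/NEO reporter, was given 1 of 5 treatments. These were the solvent DMSO, the DNA methyltransferase inhibitor decitabine (DAC, 500 nM for 72 h), the histone deacetylase inhibitors SB939 (pracinostat, 500 nM for 18 h) and SAHA (vorinostat, 1500 nM for 18 h), and DAC with SB939 at those doses and times. Cap analysis of gene expression (CAGE), which sequences the capped 5' ends of RNA, was made from 2 libraries per treatment, 10 in all. Whole-genome bisulfite sequencing, which reads methylation at each CpG, was made from 1 library each of DMSO, DAC, SB939 and DAC+SB939. The remaining 76 of the 90 samples were chromatin immunoprecipitations, not analysed here.

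The CAGE table held 76581 start-site clusters, each with the authors' mean of the normalized tags of both libraries of a treatment. Summed over clusters these means gave 12000186 tags in DMSO, 11636607 in DAC, 11542573 in SB939, 12273061 in SAHA and 14065194 in DAC+SB939. They are given below as TPM, the authors' value divided by 12.3 in every treatment. A cluster reached 1 TPM in 20612 cases in DMSO, 22270 in DAC, 23919 in SB939, 21464 in SAHA and 27106 in DAC+SB939. Of the 33919 clusters that reached 1 TPM in any treatment, 21777 (64.2%) lay within 500 bp of an annotated start on the same strand. Values of the single libraries were recovered from the means, and log2 changes below carry a standard error (SE) from limma fitted to those 2 libraries per treatment. Nothing states that the libraries came from separate cultures, so the p-values measure only the spread between libraries, which may be technical.

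To see which start sites opened when DNA methylation was lost, DAC was compared with DMSO. The promoter of CRIP1, which encodes a small LIM-domain zinc-binding protein, was listed at 0 in DMSO and at an authors' mean of 201 TPM in DAC, and its 2 DAC libraries held 190.1 and 212 TPM. This cluster lies at chromosome 14, 105953348 to 105953628, plus strand (limma, two-sided, Benjamini-Hochberg adjusted p = 6.3e-07). MAGEB2, a germ-cell antigen gene of the X chromosome, rose from 0.0271 to 184 TPM (log2 change 7.49 ± 0.15 SE), and H3C3, a replication-dependent histone H3 gene, rose from 0.0542 to 188 TPM (7.49 ± 0.17 SE). CDKN2A, which encodes the cell-cycle inhibitor p16, rose from a listed 0 to 105 TPM (chromosome 9, 21974670 to 21975267, minus strand), and KRT19, an epithelial keratin, rose from 0.0271 to 102 TPM (6.55 ± 0.40 SE). OCIAD2, SAP25 and TRIM55 rose from 0.0542 TPM or less to 116, 79.2 and 75.3 TPM.

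The falls with DAC were fewer and included several histone genes. H2BC18 fell from 197 to 37 TPM (log2 change -2.38 ± 0.17 SE), and H2BC21 from 362 to 70.6 TPM (-2.34 ± 0.21 SE). H2BC9 fell from 614 to 144 TPM (-2.08 ± 0.17 SE), and H1-4, a linker histone gene, from 716 to 154 TPM (-2.21 ± 0.15 SE). A cluster assigned to YME1L1, a mitochondrial protease gene, fell from 114 to 0.247 TPM, and it was also lower in every other treatment. DAPK1, a death-associated kinase gene often silenced by methylation in tumours, was listed at 0 in DMSO and rose to 15.4 TPM (chromosome 9, 90112774 to 90112832, plus strand; adjusted p = 4.5e-06 with limma and Benjamini-Hochberg). UHRF1 and DNMT1, which maintain methylation at replication, did not pass limma's test in DAC, with log2 changes of -0.72 (Benjamini-Hochberg adjusted p = 0.052) and -0.58 (adjusted p = 0.24).

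Among the gene lists fixed before the data were examined, cancer-testis antigens, normally expressed in germ cells, rose with DAC. Of 26 members tested, 16 rose and 2 fell in DAC, and 17 and 2 when adjusted over the list alone. The list has 43 genes, and a gene silent in DMSO was tested only where a treatment raised it, which favours rises. The list's median log2 change was 1.09, against a central 95% of -0.16 to 0.15 in 10000 random lists matched on expression, and the camera set test gave an adjusted p = 4.5e-16 (adjusted p = 0.0291 with an estimated correlation). SYCP3, a protein of the synaptonemal complex, rose from a listed 0 to 24.9 TPM, PAGE5 from a listed 0 to 54.9 TPM, and MAEL, which acts in the piRNA pathway, from a listed 0 to 8.0 TPM. Of 30 proliferation genes none rose and 19 fell (28 adjusted over the list alone). TYMS, the thymidylate synthase gene, fell from 268 to 108 TPM (-1.32 ± 0.17 SE), and UBE2C, a ubiquitin ligase partner of mitosis, fell from 430.4 to 236 TPM (-0.86 ± 0.13 SE). That list had an adjusted p = 1.4e-16 with camera (adjusted p = 0.0628 with an estimated correlation). Replication-dependent histones split, with 3 of 12 rising and 9 falling both over all clusters and adjusted over the list alone, and adjusted p = 9.7e-04 with camera (adjusted p = 0.102 with an estimated correlation). H3C1 rose from a listed 0 to 70.3 TPM and H1-1 from a listed 0 to 32.0 TPM, in contrast with the median log2 change of -1.51 over the 18 measured.

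Other lists held fewer calls in DAC. Of 12 epithelial-mesenchymal genes 4 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.102 with an estimated correlation). Among them were CLDN4, a tight-junction claudin (2.25 ± 0.29 SE), and SNAI1, a repressor of epithelial genes (from 1.41 to 4.09 TPM). Imprinted genes had 3 of 11 rising and none falling (5 and 0 adjusted over the list alone; camera adjusted p = 6.98e-04, and adjusted p = 0.0874 with an estimated correlation). NNAT, a neuronal proteolipid, was listed at 0 in DMSO and held 5.54 TPM in DAC. Of 7 metallothioneins, which bind zinc and copper, 2 rose (2 adjusted over the list alone; camera adjusted p = 0.00764, and adjusted p = 0.16 with an estimated correlation). Over the 9 measured the median of 0.13 changed sign when the median of all clusters was set to 0. Genes reported to answer deacetylase inhibitors had 3 of 15 rising and none falling (6 and 1 adjusted over the list alone; camera adjusted p = 9.7e-04, and adjusted p = 0.102 with an estimated correlation). Interferon-response genes had 3 of 19 rising and 1 falling (4 and 1 adjusted over the list alone), and antigen-presentation genes 3 of 12 rising and none falling (4 and 0 adjusted over the list alone). Genes silenced by methylation in tumours had 3 of 19 rising and none falling (3 and 0 adjusted over the list alone), among them HIC1, a transcriptional repressor, from 0.244 to 10.9 TPM. Rises and falls numbered 2 and 1 of 20 for p53 targets (4 and 2 adjusted over the list alone) and 1 and 1 of 14 for ATF4 stress genes (1 and 2). Cholesterol synthesis had 2 and 0 of 16 (2 and 0), neuronal genes 3 and 0 of 23 (3 and 0), and the epigenetic machinery 1 and 2 of 35 (1 and 3).

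Counted by size alone, 1456 clusters were at least 2-fold higher and 307 at least 2-fold lower in DAC, and 473 and 23 passed 4-fold. With limma, 1883 clusters rose and 674 fell of 32321 tested. After the median log2 level of all clusters was set to 0 in each treatment, the same size rule gave 1209 higher and 541 lower, and limma 1359 and 771. In simulated libraries with the measured spread and 200 changed clusters, this comparison recovered 18% of 2-fold and 89% of 4-fold changes. The adjusted threshold is stricter when few clusters change, so these shares do not give the detection limit of the measured comparison. Of its 2557 calls 1533 were at least 2-fold, and the rest were smaller. Neither the fit nor the simulation takes account of depth order. With depth order as a replicate block limma called 2386 rises and 1142 falls. Without the deeper DMSO library limma called 1195 rises and 243 falls, without the shallower DMSO library 1104 and 203, without the deeper DAC library 1195 and 387 and without the shallower DAC library 1291 and 199. By size the falls past 2-fold numbered 661 without the deeper DAC library.

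To see which start sites answered inhibition of histone deacetylases alone, SB939 was compared with DMSO. DHRS2, a short-chain dehydrogenase gene known to answer deacetylase inhibitors, rose from 2.69 to 274 TPM (chromosome 14, 24105569 to 24105833, plus strand; log2 change 6.22 ± 0.13 SE, adjusted p = 6.6e-08 with limma and Benjamini-Hochberg). ACSBG1, an acyl-CoA synthetase gene, rose from 0.403 to 138 TPM (chromosome 15, 78537853 to 78538031, minus strand; 6.64 ± 0.14 SE). ARRDC4, an arrestin-domain gene, rose from 0.674 to 106 TPM, and MIR7-3HG, the host transcript of a microRNA, from a listed 0 to 66.8 TPM. CDKN1A, which encodes the cell-cycle inhibitor p21, rose from 65.7 to 372 TPM (chromosome 6, 36646432 to 36646545, plus strand; 2.49 ± 0.18 SE, adjusted p = 3.9e-05 with limma and Benjamini-Hochberg). In the other direction, HMGA2, a chromatin-bound oncofetal protein gene, fell from 675 to 25.4 TPM (chromosome 12, 66217926 to 66219219, plus strand; -4.68 ± 0.11 SE). FOSL1, a subunit of the AP-1 transcription factor, fell from 275 to 5.84 TPM (chromosome 11, 65667710 to 65668083, minus strand; -5.34 ± 0.14 SE).

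Further falls with SB939 included MIR100HG, a microRNA host transcript, from 76.8 to 0.683 TPM (-5.53 ± 0.16 SE), G0S2, an inhibitor of lipolysis, from 282 to 5.64 TPM (-5.38 ± 0.53 SE). PLAU, the urokinase protease gene, fell from 54.8 to 0.444 TPM, and HOXB2, a homeobox gene, from 88.6 to 3.11 TPM. Clusters assigned to MORF4L1 and NPC1, a chromatin adaptor and a cholesterol transporter gene, rose from 0.0813 and 0.282 TPM to 92.4 and 58.9 TPM. They lie at annotated starts that belong to the repeated sequence described below as family A. They need not be the main starts of these genes, and other starts are not given here. A strong rise without an annotated start stood in an intron of ETV7 (chromosome 6, 36331147 to 36331403, minus strand), where 1.22 TPM in DMSO became 469 TPM in SB939 (7.72 ± 0.14 SE). A cluster in an exon of CLU, the clusterin gene (chromosome 8, 27467990 to 27468163, minus strand), had authors' means of 0.834 TPM in DMSO, 633 TPM in SB939 and 274 TPM in SAHA. It was too high in the combination, at 2738 TPM, for its libraries to be recovered. UHRF1 fell from 41.9 to 3.16 TPM (-3.37 ± 0.18 SE) and DNMT1 from 111 to 46.1 TPM (-1.27 ± 0.24 SE, adjusted p = 0.0038 with limma and Benjamini-Hochberg).

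By list, 11 of 15 genes reported to answer deacetylase inhibitors rose with SB939 and 1 fell (12 and 1 adjusted over the list alone). Over the 18 measured the median log2 change was 1.31, against -0.58 to 0.35 in random lists. CCN2, a matricellular protein, rose from 14.4 to 110 TPM (2.84 ± 0.17 SE). Camera gave the list an adjusted p = 4.85e-05 (adjusted p = 0.152 with an estimated correlation). Of 23 neuronal genes 15 rose and none fell, with the same numbers adjusted over the list alone (camera adjusted p = 4.08e-05, and adjusted p = 0.152 with an estimated correlation). Cholesterol-synthesis genes rose in 12 of 16 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00146, and adjusted p = 0.569 with an estimated correlation). HMGCS1, an early enzyme of that pathway, rose from 28.6 to 341 TPM (3.53 ± 0.20 SE), and FDFT1, squalene synthase, from 84.0 to 361 TPM. The authors' mean of INSIG1, a feedback regulator of the pathway, was 44.9 TPM in DMSO and 945 TPM in SB939. Proliferation genes fell in 28 of 30 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 5.78e-10, and adjusted p = 0.152 with an estimated correlation). TYMS fell to 30.6 TPM (-3.09 ± 0.17 SE) and FOXM1, a mitotic transcription factor, from 86.4 to 13.0 TPM (-2.64 on the log2 scale).

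The epigenetic machinery fell more often than it rose with SB939, with 5 rising and 16 falling of 35 (6 and 21 adjusted over the list alone). HDAC7 fell from 14.4 to 1.34 TPM and HDAC5 rose from 10.3 to 31.8 TPM, both deacetylase genes of the same class. Interferon-response genes went both ways, 6 rising and 6 falling of 19 (6 and 8 adjusted over the list alone). So did antigen presentation with 3 and 4 of 12 (3 and 4) and p53 targets with 6 and 4 of 20 (6 and 5). ATF4 stress genes had 4 and 3 of 14 (4 and 4) and methylation-silenced genes 3 and 4 of 19 (2 and 4). Cancer-testis antigens had 1 rising and 6 falling of 26 (1 and 5 adjusted over the list alone), and replication-dependent histones 1 and 5 of 12 (2 and 5). For epithelial-mesenchymal genes the numbers were 1 and 2 of 12 (1 and 2), for metallothioneins 1 and 0 of 7 (1 and 0), and for imprinted genes 2 and 1 of 11 (2 and 1). ZEB2, a repressor of E-cadherin, fell from 14.6 to 1.71 TPM while SNAI1 rose from 1.41 to 13.1 TPM.

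By size, 5306 clusters were at least 2-fold higher and 3648 at least 2-fold lower in SB939, with 1079 and 583 past 4-fold, and limma called 7371 rises and 6203 falls. With the median of all clusters set to 0, falls outnumbered rises, 5377 against 3446 by size and 8045 against 4709 with limma, and quantile normalization gave 4480 higher and 4274 lower by size and 5967 rises and 6882 falls with limma. The deeper SB939 library stood apart in exon tags, with 6.04% of its tags in exon clusters against 3.08% in the shallower SB939 library and at most 3.50% in the other 8. The SB939 libraries correlated at 0.965, those of DAC+SB939 at 0.966 and those of SAHA, DMSO and DAC at 0.981, 0.982 and 0.982. An SB939 and a SAHA library correlated at 0.979, above the SB939 pair. Without the shallower DMSO library limma called 4774 rises and 4624 falls in SB939.

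SAHA, dosed higher than SB939 but for the same time, was compared with DMSO in the same way. DHRS2 rose to 294 TPM (log2 change 6.32), ACSBG1 to 164 TPM (6.87, adjusted p = 4.5e-08 with limma and Benjamini-Hochberg), ARRDC4 to 119.8 TPM (6.17) and CDKN1A to 392 TPM (2.57). HMGA2 fell to 24.8 TPM (-4.71), FOSL1 to 4.52 TPM (-5.64), MIR100HG to 0.510 TPM (-5.69) and TYMS to 32.3 TPM (-3.02). RFLNA, a filamin-interacting protein gene, fell from 24.8 to 0.234 TPM (-4.38). By size 4636 clusters were at least 2-fold higher and 3389 lower, and 1160 and 507 passed 4-fold, while limma called 7398 rises and 5505 falls. With the median of all clusters set to 0, the size rule gave 3974 higher and 4020 lower and limma 6126 and 6087.

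Of 15 genes reported to answer deacetylase inhibitors, 10 rose in SAHA and 1 fell (12 and 1 adjusted over the list alone). Camera gave this list an adjusted p = 4.05e-04 (adjusted p = 0.192 with an estimated correlation). Neuronal genes rose in 15 of 23 cases with no fall, also adjusted over the list alone (camera adjusted p = 1.63e-04, and adjusted p = 0.192 with an estimated correlation). Cholesterol synthesis rose in 12 and fell in 1 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.00216, and adjusted p = 0.598 with an estimated correlation). HMGCS1 rose to 396 TPM (3.74). Proliferation genes rose in 2 and fell in 26 of 30 cases (2 and 27 adjusted over the list alone). Their adjusted p was 1.34e-10 with camera (adjusted p = 0.192 with an estimated correlation). UHRF1 fell to 5.08 TPM (-2.83). Rises and falls were 8 and 14 of 35 for the epigenetic machinery (8 and 16 adjusted over the list alone). They were 6 and 5 of 19 for interferon response (7 and 6) and 4 and 3 of 12 for antigen presentation (5 and 3). For p53 targets they were 7 and 4 of 20 (9 and 4), for ATF4 stress 5 and 3 of 14 (6 and 4) and for methylation-silenced genes 4 and 4 of 19 (4 and 4). For cancer-testis antigens they were 3 and 4 of 26 (2 and 4) and for replication-dependent histones 2 and 5 of 12 (2 and 5). Epithelial-mesenchymal genes had 1 and 2 of 12 (1 and 2), metallothioneins 1 and 0 of 7 (1 and 0), and imprinted genes 4 and 1 of 11 (4 and 1).

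SB939 at 500 nM and SAHA at 1500 nM were then set side by side, both after 18 h, so the doses differed. At HMGA2 the SB939 minus SAHA difference was 0.03 on the log2 scale (95% interval -0.22 to 0.28) and at DHRS2 -0.10 (-0.40 to 0.20). The difference was -0.08 at CDKN1A (-0.50 to 0.35), -0.07 at TYMS (-0.47 to 0.32) and -0.21 at HMGCS1 (-0.66 to 0.25). The widest gap among the genes listed here was at UHRF1, with -0.53 (-0.95 to -0.11, adjusted p = 0.312 with limma and Benjamini-Hochberg), which did not pass the test. Other named genes had wider gaps that did not pass either. Among them were PPIB, higher in SB939 with 1.42 (0.34 to 2.51), and MEG3, higher in SAHA with -0.83 (-1.51 to -0.16). Over all 32321 clusters the median half-width of the interval was 0.52, and 73.7% of intervals lay within 2-fold in both directions. An unadjusted p under 0.05 with limma was reached by 4123 of them. Limma called 42 clusters, 27 higher in SB939 and 15 higher in SAHA, whose median values in the lower compound were 0 TPM, with 41% and 40% of them in exons. Without the shallower SB939 library the calls numbered 582, and without the deeper SB939, the deeper SAHA or the shallower SAHA library 24, 24 and 23. By size 1608 clusters were at least 2-fold higher in SB939 and 37 in SAHA; 51.1% of the former lay in exons, and they held a median of 5.28 TPM in the deeper SB939 library and 2.37 TPM in the shallower. Without the deeper SB939 library 512 were higher in SB939 and 183 in SAHA, without the shallower SB939 library 3567 and 66, without the deeper SAHA library 2499 and 96 and without the shallower SAHA library 1583 and 64.

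Across clusters, which are not independent replicates, the log2 changes of SB939 and SAHA correlated at 0.911 with a covariance of 0.930. Both comparisons used the same DMSO libraries, and simulated unchanged groups against shared controls gave a correlation of 0.497 and a covariance of 0.0401. With a different DMSO library for each compound the observed correlation was 0.828 and the covariance 0.883. Of the rises, 5769 were shared against 1687 for independent lists, and of the falls 4938 against 1057; part of that excess can come from the shared DMSO libraries, since a split left only 1 control library per compound.

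DAC and SB939 together gave the broadest response of the series, and it was led by transcripts that neither agent alone had raised as far. LINC01882, a long non-coding RNA, rose from 0.0542 to 622 TPM (chromosome 18, 12776128 to 12776170, minus strand; log2 change 9.21 ± 0.15 SE, adjusted p = 6.5e-09 with limma and Benjamini-Hochberg). TM4SF18-AS1 rose from 0.163 to 795 TPM (9.43 ± 0.19 SE) and CCDC13-AS2 from a listed 0 to 482 TPM. MEG3, a maternally expressed imprinted RNA, was listed at 0 in DMSO, held 27.9 TPM in DAC and 0.245 TPM in SB939, and rose to 559 TPM in the combination (chromosome 14, 101292441 to 101292538, plus strand). MAGEB2 rose to 361 TPM and CRIP1 to 284 TPM. TNFRSF1A, a receptor of tumour necrosis factor, fell from 258 to 14.9 TPM (-4.02 ± 0.13 SE), HMGA2 from 675 to 26.9 TPM (-4.60 on the log2 scale) and UHRF1 from 41.9 to 2.63 TPM (-3.56 ± 0.18 SE).

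Every tested metallothionein rose in the combination, 7 of 7, also adjusted over the list alone, with a median log2 change of 5.24. The list has 12 genes, and those silent in DMSO were tested only where a treatment raised them. Over the 9 measured the median was 3.67, against -0.71 to 1.05 in random lists (camera over the tested 7, adjusted p = 7.7e-05, and adjusted p = 0.122 with an estimated correlation). MT1A rose from 0.0271 to 180.0 TPM (7.46 ± 0.19 SE), and MT1G from a listed 0 to 77.8 TPM. Neuronal genes rose in 19 of 23 cases with no fall, also adjusted over the list alone (camera adjusted p = 5.04e-07, and adjusted p = 0.122 with an estimated correlation). CHGA, the secretory-granule protein chromogranin A, rose from 0.2 to 250.4 TPM (7.73 ± 0.23 SE). Genes reported to answer deacetylase inhibitors rose in 14 of 15 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 2.01e-05, and adjusted p = 0.122 with an estimated correlation). CCN2 rose to 766 TPM (5.64 ± 0.17 SE). Of 26 cancer-testis antigens 19 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 2.91e-04, and adjusted p = 0.122 with an estimated correlation), and SYCP3 rose to 108 TPM. Imprinted genes rose in 8 and fell in 1 of 11 cases (8 and 2 adjusted over the list alone; camera adjusted p = 0.00983, and adjusted p = 0.137 with an estimated correlation). H19 rose from a listed 0 to 28.4 TPM. Proliferation genes fell in 26 of 30 cases and rose in 3 (3 and 27 adjusted over the list alone; camera adjusted p = 1.02e-07, and adjusted p = 0.122 with an estimated correlation).

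Immune genes rose in part. Of 19 interferon-response genes 10 rose and 3 fell (10 and 5 adjusted over the list alone), with a median log2 change of 0.50 that was inside the random range of -0.46 to 0.82 and became -0.10 when the median of all clusters was set to 0. IRF7, a transcription factor of the interferon response, rose from 4.11 to 193 TPM (5.25 ± 0.21 SE), and IFI6, an interferon-induced membrane protein, from 28.4 to 362 TPM (3.60 ± 0.24 SE). Antigen presentation had 8 rising and 3 falling of 12, also adjusted over the list alone. CD74, the class II invariant chain, rose from 0.0271 to 28.8 TPM (4.86 ± 0.19 SE), and TAP2, a peptide transporter, fell from 35.7 to 11.8 TPM (-1.52 on the log2 scale). Of 19 methylation-silenced genes 10 rose and 4 fell, of 20 p53 targets 11 and 4, and of 14 ATF4 stress genes 7 and 4, each also adjusted over the list alone. GDF15, a stress cytokine and p53 target, rose from 0.121 to 11.2 TPM (3.45 on the log2 scale), CDKN1A from 65.7 to 310.0 TPM (2.22 ± 0.18 SE) and ATF3, a stress transcription factor, from 1.47 to 30 TPM (3.66 ± 0.18 SE). TFPI2, a protease inhibitor often silenced by methylation, had authors' means of 55.5 TPM in DMSO and 1598 TPM in the combination and was not tested. Cholesterol synthesis had 9 rising and 4 falling of 16 (9 and 5 adjusted over the list alone). Epithelial-mesenchymal genes rose in 7 and fell in 2 of 12 cases (7 and 2), and the epigenetic machinery in 9 and 13 of 35 (9 and 13). Replication-dependent histones rose in 4 and fell in 8 of 12 cases (4 and 8), with a median log2 change of -1.05 and a mean of 0.17 over these 12, and a median of -1.15 and a mean of -0.46 over the 18 measured.

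By size, 9548 clusters were at least 2-fold higher and 3710 lower in the combination, 3857 and 614 passed 4-fold, and limma called 11315 rises and 6407 falls. The median log2 change of all 33919 clusters stood at 0.26 in the combination. Setting the median log2 level of each treatment to 0 shifted changes by more than that. Over the 30165 clusters counted by size the median change went from 0.31 to -0.29, which favours falls. The balance then turned to 5335 higher and 8657 lower by size and to 7404 rises and 12138 falls with limma. Quantile normalization gave 6410 higher and 6686 lower by size and 8287 rises and 10950 falls with limma.

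**Figure D1:**
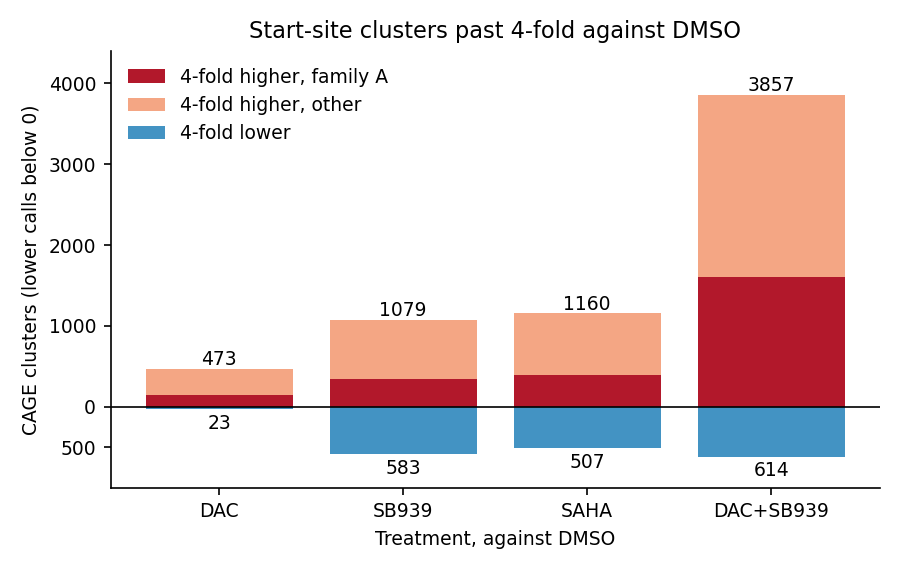
Number of start-site clusters past 4-fold in each treatment against DMSO, with higher clusters above 0, split into family A (dark) and others, and lower clusters below 0. Of the 3857 higher clusters in the combination 1608 were in family A, and of the 473 in DAC 148.

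What each agent added to the other was asked by comparing the combination with DAC and with SB939. Against DAC, 8264 clusters were at least 2-fold higher and 3338 lower, and 3145 and 438 passed 4-fold; limma called 10407 rises and 6159 falls. Against SB939 the numbers were 5828 and 1040, with 2532 and 29 past 4-fold, and limma called 6998 rises and 1632 falls. The falls against SB939 depended on single libraries: by size they numbered 636 without the deeper and 2521 without the shallower SB939 library, and 1546 and 1757 without the deeper and the shallower library of the combination. In the same order 23, 137, 68 and 158 passed 4-fold, and limma called 1157, 2064, 940 and 826. With the median of all clusters set to 0 the size rule gave 4999 higher and 7343 lower against DAC and 4138 and 3264 against SB939, and limma 7047 and 10721, and 5317 and 5151. Quantile normalization gave 5706 and 5783 by size and 7908 and 10063 with limma against DAC, and 4246 and 2685, and 5563 and 6474, against SB939.

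Whether the combination exceeded the summed log2 changes of its parts was tested as an interaction. CHGA stood 5.99 ± 0.32 SE above that sum on the log2 scale, MT1A 5.50 ± 0.27 SE and CGA, the shared subunit of glycoprotein hormones, 5.08 ± 0.27 SE. CCDC13-AS2 (adjusted p = 7.5e-06 with limma and Benjamini-Hochberg), MT1G and MEG3, listed at 0 in DMSO, also lay above it. IRF7 stood 2.97 ± 0.30 SE above and CD74 3.12 above. CDKN2A stood below the sum (adjusted p = 0.00029 with limma and Benjamini-Hochberg), as its 105 TPM in DAC were 15.5 TPM in the combination, and so did DAPK1, FDFT1 (-2.27) and TM4SF18-AS1 (-1.98). By size 5139 clusters lay at least 2-fold above the sum and 1904 below, and limma called 4898 above and 890 below. By size 3511 lay below without the shallower SB939 library and 1246 without the deeper. With limma 1372 lay below without the shallower SB939 library, 512 and 463 without the deeper and the shallower DMSO library, and 564 and 501 without the deeper and the shallower DAC library. With depth order as a replicate block 5620 lay above and 1485 below. With the median of all clusters set to 0, the numbers were 3849 and 3295 by size and 3872 and 1410 with limma, and with quantile normalization 3700 and 3121, and 4076 and 2517.

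To find start sites that were silent in solvent, clusters listed at 0 in DMSO were counted that reached 1 TPM in both libraries of a treatment. There were 588 in DAC, 650 in SB939, 747 in SAHA and 4014 in DAC+SB939. The highest in DAC was CRIP1 at 201 TPM. Of the 4014 in the combination, 74.1% lay over 500 bp from any annotated start, the median level was 3.79 TPM and the highest 790.03 TPM. As background, clusters at 0 in the shallower DMSO library and at 1 TPM or more in the deeper numbered 145, and 4 the other way round. Without the deeper DMSO library the counts were 862 in DAC, 1468 in SB939, 1500 in SAHA and 5185 in DAC+SB939.

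Many of these sites shared one sequence. Among the 3857 clusters past 4-fold in the combination, 1675 (43.4%) fell into a single group of similar sequences, and 91.2% of those lay over 500 bp from an annotated start. The series title names long terminal repeats as the sites of interest, and no repeat annotation was used here. Near copies of the group's seed sequence across the genome held 2705 clusters, called family A here. Membership thus follows from position at a copy, and 1608 of the 3857 clusters meet it. Family A took 0.0316% of all tags in DMSO, 0.343% in DAC, 1.69% in SB939, 1.94% in SAHA and 8.72% in DAC+SB939. Over the 2698 of its clusters recovered in every library, both libraries of each treatment gave similar sums, 249 and 239.5 TPM in DMSO, 2989 and 2549.7 in DAC, 14465 and 12751 in SB939, 16780 and 16391 in SAHA, and 97741 and 84041 in the combination. Of 4526 sense copies, 30 reached 1 TPM in DMSO, 306 in DAC, 567 in SB939, 633 in SAHA and 2079 (45.9%) in the combination, while 1 did so on the antisense strand in the combination.

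Single members of family A reached the levels of abundant genes. A cluster in an intron next to CDKN2A-DT (chromosome 9, 21959869 to 21960253, plus strand) had authors' means of 0.108 TPM in DMSO, 110.0 TPM in DAC, 38.3 TPM in SB939 and 1795 TPM in the combination. A second intergenic member (chromosome 6, 153455505 to 153455792, plus strand) was listed at 0 in DMSO and rose to 74.3 TPM in DAC, to 13.3 TPM in SB939 and to 633 TPM in the combination. Members made up 148 of the 473 clusters past 4-fold upward in DAC, 343 of 1079 in SB939, 391 of 1160 in SAHA and 1608 of 3857 in the combination, and 143, 286, 339 and 1686 of the clusters not seen in DMSO (216, 437, 498 and 1913 without the deeper DMSO library). Their median log2 change was 2.63 in the combination, 2.03 with the median of all clusters set to 0 and 2.16 after quantile normalization. In DAC, SB939 and SAHA it was 0.03, 0.11 and 0.15, with -0.10, -0.14 and 0.04 under the former setting and 0, 0.06 and 0.19 under the latter. These medians depend on the pseudocount, since 87.5% of members were listed at 0 in DMSO: with 0.1 TPM they were 0.24, 0.86, 1.04 and, in the combination, 5.57, and with 5 TPM 0.005, 0.02, 0.03 and 1.03. A second group, family B (seed at chromosome 5, 56597912 to 56598261, minus strand, intergenic), held 886 clusters with 0.0125% of tags in DMSO, 0.0638% in DAC, 0.0363% in SB939 and 0.336% in the combination.

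**Figure D2:**
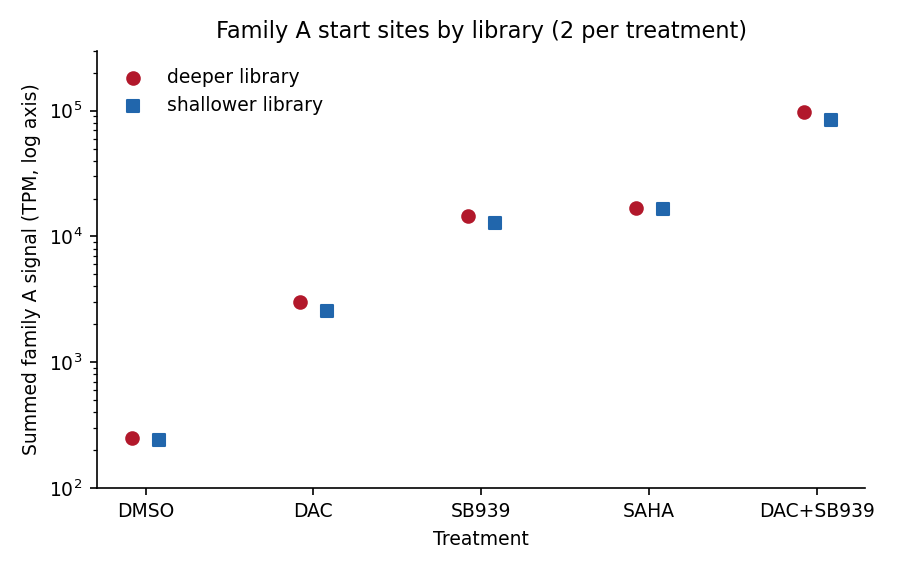
Summed signal of the 2698 family A clusters, in TPM on a log axis, in the deeper and shallower recovered library of each of the 5 treatments. The sums were 249 and 240 TPM in DMSO, 2989 and 2550 in DAC, 14465 and 12751 in SB939, 16780 and 16391 in SAHA and 97741 and 84041 in DAC+SB939.

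Named gene starts inside family A included DHRS2, ACSBG1, MORF4L1, NPC1 and LINC01882, and also GBP5 and ZNF80 of a list of genes reported to start in the LTR12 repeat. Of that list's 7 genes 4 were tested, and the tested starts of TNFRSF10B and AXIN1 lay outside family A. In the combination 2 rose and 1 fell, also adjusted over the list alone. GBP5, a guanylate-binding protein gene, rose from a listed 0 to 5.48 TPM and ZNF80, a zinc-finger gene, from a listed 0 to 2.44 TPM. TNFRSF10B, a death receptor gene, fell from 21.9 to 6.69 TPM (-1.57 ± 0.14 SE). AXIN1, a Wnt pathway scaffold gene, had a log2 change of 0.34 (adjusted p = 0.29 with limma and Benjamini-Hochberg). Rises and falls on that list numbered 0 and 1 in DAC, 1 and 1 in SB939 and 1 and 1 in SAHA, also adjusted over the list alone. The GBP5 call in SB939 ended without either DMSO library or the deeper SB939 library, and that of TNFRSF10B without the shallower DMSO library (log2 change -0.70 in DAC and -0.56 in SB939) or the shallower DAC library (-0.77). TP63, a p53 relative with a start reported in such a repeat, was listed at 0 in all but the combination, where its authors' mean was 0.537 TPM, and was not tested.

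Bisulfite sequencing was read to see how much methylation each treatment removed. Over the 23512556 CpGs with at least 5 calls in all 4 libraries, 60.3% of calls were methylated in DMSO, 26.1% in DAC, 52.9% in SB939 and 25.2% in DAC+SB939. Over all 28162537 CpGs the mean depths were 16.3, 14.3, 15.2 and 14.6 calls per CpG. The 95% Wilson intervals, which cover counting error only, were 60.339 to 60.349, 26.063 to 26.072, 52.851 to 52.861 and 25.186 to 25.195%. Differences from DMSO were -34.3 percentage points in DAC, -7.49 in SB939 and -35.2 in the combination. The median CpG stood at 80% in DMSO, 27.8% in DAC, 66.7% in SB939 and 26.7% in the combination, and CpGs above 80% methylation made up 49.8%, 0.562%, 33.8% and 0.469%. With 1 library per treatment these differences have no replicate check, and Fisher's exact test compares the libraries, not the treatments. That test (two-sided, Benjamini-Hochberg, at least 20 points) found 10338026 CpGs lower and 378 higher in DAC of 24649427, 23 lower and 0 higher in SB939 of 25135795, and 10785762 lower and 342 higher in the combination. A difference of -7.49 points at a CpG is below the 20-point rule. At these depths and with adjustment over all CpGs the test also had little power for it. The count in SB939 therefore does not show that few CpGs changed.

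In each treated library methylation was lower than in DMSO for every class of sequence by annotation, CpG density or family. Promoter windows went from 45.2% in DMSO to 21.7% in DAC, 39.8% in SB939 and 21.5% in the combination, gene bodies from 70.7% to 30.7, 62.4 and 29.7%, and intergenic sequence from 51.8% to 22.1, 45.1 and 21.2%. CpG-dense sequence held 26.4% in DMSO and 15% in DAC, and CpG-poor sequence 56.9% and 23.4%. Copies of family A went from 67.3% in DMSO to 31.8% in DAC, 60.6% in SB939 and 30.9% in the combination, and those of family B from 46.4% to 20.3, 39.9 and 19.5%. Of 26738 bins of 100 kb, all were lower than in DMSO in DAC and the combination, and 99.9% in SB939.

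**Figure D3:**
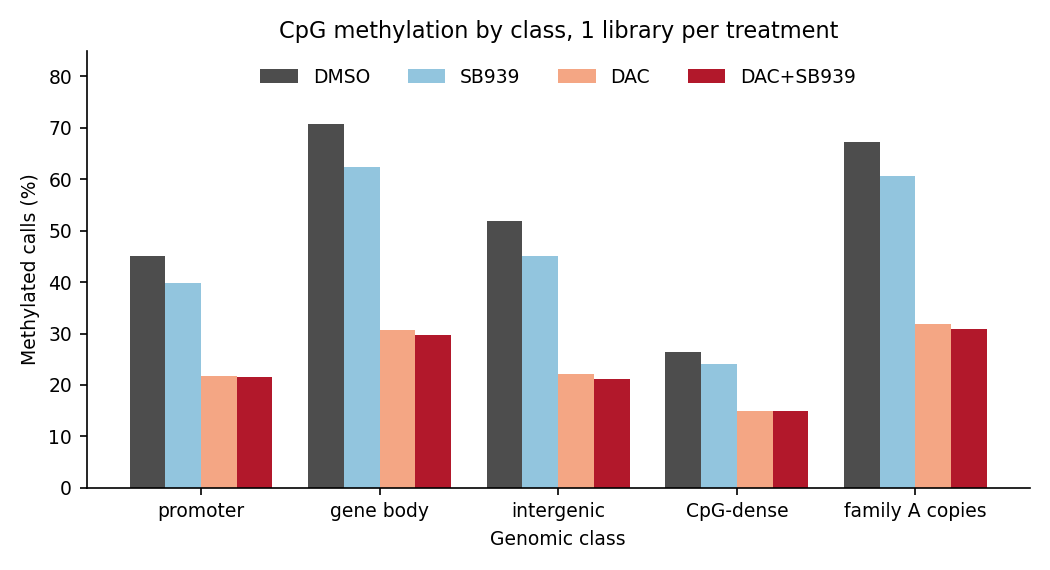
Percentage of methylated calls in the DMSO, SB939, DAC and DAC+SB939 libraries, 1 per treatment, by class of sequence. Family A copies stood at 67.3% in DMSO, 31.8% in DAC, 60.6% in SB939 and 30.9% in DAC+SB939.

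Most start sites that rose at least 4-fold in DAC lay in methylated sequence, with 351 at DMSO levels of 80% or more and 16 under 20%. Around the 462 clusters past 4-fold upward in DAC the mean level within 500 bp was 82.9% in DMSO and 39.5% in the DAC library, against 34.6% in DMSO around 15974 clusters under 2-fold. Medians in DMSO were 90.2% and 5.63%, and pooled calls gave 82.3% and 17.1%. The promoters of CRIP1, MAGEB2, H3C3 and CDKN2A went from 93.0, 93.8, 96.5 and 100% in DMSO to 33.4, 42.7, 48.3 and 46.9% in DAC, DAPK1 from 64.4 to 32.5% and MEG3 from 81.2 to 37.6%. Clusters past 4-fold upward in SB939 and SAHA had DMSO means of 48.5% and 42.9%, and within the SB939 set the median was 7.41% at annotated starts and 81.3% over 500 bp from them. Around the 3790 clusters past 4-fold upward in the combination the DMSO mean was 62.2% and the median 76.0%, with a median of 85% for family A and 49.2% for clusters outside the families. Clusters past 4-fold downward in SB939 and in the combination lay in sequence with DMSO medians of 0.752% and 0.627%.

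Clusters at 1 TPM or more in any treatment were grouped by their methylation level in DMSO. A cluster silent in DMSO entered only where a treatment raised it. This filter raises the shares in classes that hold many such clusters, so the shares are not rates over all methylated sites. Of 17580 clusters under 20% methylation, 0.0910% passed 4-fold upward in DAC, 2.21% in SB939 and 4.16% in the combination. Of 2162 clusters between 60 and 80% these shares were 3.15, 6.66 and 34.9%, and of 10379 clusters above 80% they were 3.38, 3.47 and 16.3%. Outside the families the shares in these 3 classes were 0.0913, 3.02 and 2.27% in DAC, 2.15, 2.88 and 1.88% in SB939 and 4.04, 19.6 and 6.57% in the combination. Copies of family A that reached 1 TPM in DAC had a mean DMSO level of 84.4% (299 copies), those that reached it in SB939 75.4% (558). Those that reached it only with DAC present had 78.7% (1398), and those that stayed below it 58.9% (2138).

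**Figure D4:**
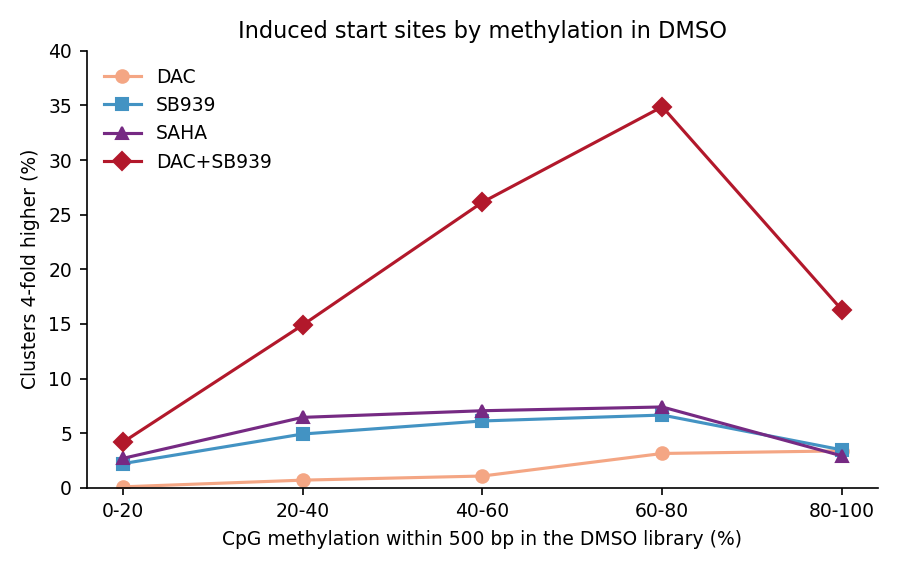
Percentage of clusters past 4-fold upward in each treatment by the methylation level of the surrounding sequence in DMSO, in classes of 20 percentage points. Only clusters at 1 TPM or more in any treatment were counted, so those silent in DMSO entered only where a treatment raised them. In the combination the share was 4.16% in the lowest class, 34.9% between 60 and 80% and 16.3% in the highest class.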

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

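The tests of even loss, of mixed DNA and of uneven sampling for SB939 methylation, and those of scaling and pseudocount for the combination, were chosen only after the results were seen, as was the test on recovered libraries.

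The response to DAC+SB939 differed from the sum of DAC and SB939 at 5788 clusters, which is why this result is taken up again. CHGA, MT1A, MT1G and CCDC13-AS2 were among them. By limma's interaction term (Benjamini-Hochberg, two-sided) the effect of 1 agent depended on the other, with 4898 clusters above the sum and 890 below. The number below changed when single libraries were left out, as given above. Family A held 1738 clusters above the sum and 50 below among its 2011 tested. The family was found among clusters past 4-fold in the combination. Of its 2705 clusters 2130 reached 1 TPM there, against 30 in DMSO, 306 in DAC and 579 in SB939. Many members thus entered the test only through the combination, which favours counts above the sum. Outside families A and B 2806 lay above and 836 below among 29875. A common scaling difference cannot carry the changes at least 4-fold from the sum, since over median centring and quantile normalization at least 85.8% of them lay above it, but for smaller ones it stays open, with 53.9% of the 2-fold changes above after median centring, and 73.3% of limma's calls above after median centring and 61.8% after quantile normalization. The pseudocount alone cannot carry the rises, since with 0.1 TPM limma's rises numbered 74.4% of those with 1 TPM, but the balance by 2-fold size depends on it, with 73.0% above at 1 TPM, 59.3% at 0.1 and 87.9% at 5, and past 4-fold at 0.1 TPM 3820 lay above and 1391 below. Clusters at the floor in DMSO are not the whole of it for limma's calls of any size. Among 20178 clusters at 1 TPM or more in DMSO 1118 lay above and 395 below the sum, 73.9% above. Most calls above the sum were nonetheless under 1 TPM in DMSO, with 3780 above and 495 below among 12143. Of these clusters 31.1% lay above the sum, against 5.54% of those at 1 TPM or more. Clusters under 1 TPM in DMSO were tested only where a treatment library reached 1 TPM, so the filter itself favours this difference. The floor was not examined for the changes at least 4-fold from the sum. For the changes at least 4-fold from the sum, a joint action of both agents is a hypothesis that was not tested. The floor in DMSO stays open for them as well. The pattern was found and examined on the same 2 libraries per treatment.

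Family A, which supplies DHRS2, ACSBG1 and LINC01882 with starts, took 8.72% of tags in the combination. Reads shared between copies identical over the first 31 bases are not needed for the rises. Of the 2165 member clusters whose first 31 bases occur once in the genome 60.6% passed 4-fold, against 54.6% of 540 others. Of all clusters at 1 TPM or more in a treatment 11.4% did. Only exact matches were counted, so reads misplaced between copies that differ by few bases stay possible. The family was found among clusters past 4-fold in these libraries, so part of its high share follows from that choice. A few copies do not carry it, as the 10 strongest held 11.2% of the family's tags, and scaling does not, as 84.4% of the rises were kept with the median of all clusters set to 0. The set may therefore reflect activation of many separate copies by the treatments, as a hypothesis.

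The SB939 library stood -7.49 percentage points from DMSO in methylated calls. An even loss of methylated calls would give 1 ratio to DMSO everywhere, but the ratio spanned 0.0673 over 5 classes of CpG density. A mixture with DNA of the DAC library would give a fixed share of the DAC loss, but that share spanned 0.117. Uneven sampling of CpG-dense and CpG-poor DNA would leave levels within a class alone, but the highest ratio in any class was 0.918. A treatment effect cannot be told apart from any other difference of that culture or library, because SB939 had 1 library.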

How the results depend on the processing

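The test on recovered libraries with its estimates of single genes, the deeper and shallower libraries alone, the depth-order block, voom weights and the camera tests were chosen only after the data were seen; the other alternatives were planned. Of 352 changes of named genes called with limma, 4425 of 4559 recomputed values kept direction and threshold, none reversed and 134 lost the call, chiefly without the shallower DMSO library (31), without the deeper DMSO library (21), with the median of all clusters set to 0 (14), with a pseudocount of 5 (10) and, of 70 calls in DAC, without the deeper (10) or the shallower DAC library (11). Many named genes were chosen for large changes in these same data, so part of this stability follows from the choice. It does not extend to calls in general. For the values that answer a comparison the limit was a fixed ratio for counts and shares, and counting error alone for methylation levels. By the latter, -34.1 in place of -34.28 points in DAC counted as moved. The correlation of SB939 and SAHA had no limit and was always counted as moved. The split is thus no common measure of stability. Over the 48 values that answer a comparison, 331 of 470 recomputed values stayed within the limit set and 139 moved. The counts among them have no sign, but with the median of all clusters set to 0 the balance of rises and falls past 2-fold turned in SB939, from 5306 and 3648 to 3446 and 5377, in SAHA, from 4636 and 3389 to 3974 and 4020, and in the combination, from 9548 and 3710 to 5335 and 8657. That setting moved the median change below 0, to -0.14 in SB939, -0.09 in SAHA and -0.29 in the combination, which favours falls. In SB939 the balance also turned without rescaling, to 1430 and 1519 with a pseudocount of 5 and to 2387 and 2485 at 5 TPM or more (4196 and 4430 with limma). Where a value moved, the cause was not tested, except that a stricter floor counts fewer clusters and a left-out library leaves fewer samples. Fits with paired-end libraries alone, single-end libraries alone or format as a covariate were not run, because the recovered values carry no format label. The smallest treatment differences are limited by 2 libraries per treatment in CAGE, where the lone library of a left-out pair was assumed to vary like the others, and by 1 in bisulfite sequencing.

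Clusters past 2-fold numbered 1763 in DAC, and 3217 with a pseudocount of 0.1, 501 with 5 and 777 at 5 TPM or more. For SB939 there were 8954, and 2949 with 5, 4872 at 5 TPM or more and 13574 with limma. SAHA had 8025, and 2763, 4420 and 12903 in the same order. The combination had 13258, with 5488 at a pseudocount of 5 and 7319 at 5 TPM or more, against DAC 11602, with 4691 and 6596, and against SB939 6868, with 10328 at a pseudocount of 0.1, 2601 at 5 and 3513 at 5 TPM or more. SB939 against SAHA had 1645, with 4011 at 0.1, 261 at 5, 665 at 5 TPM or more, 3204 in the deeper libraries alone, 1077 in the shallower alone, 42 with limma, and from 695 to 3633 when 1 library was left out. The combination against the sum had 7043, with 11909 at 0.1, 2461 at 5 and 3663 at 5 TPM or more. Past 4-fold, a pseudocount of 0.1 and 5 gave 1321 and 118 in DAC (main count 496), 5748 and 414 in SB939 (1662), 5192 and 408 in SAHA (1667), and 9845 and 1595 in the combination (4471).

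For limma's calls, a required change of 2-fold left 1533 of 2557 in DAC, 7934 of 13574 in SB939, 7512 of 12903 in SAHA and 10780 of 16566 for the combination against DAC. Testing only clusters at 5 TPM or more gave 8626 in SB939, 8422 in SAHA, 10364 in the combination, 9875 and 4958 for the combination against DAC and SB939, 8 for SB939 against SAHA and 3326 for the interaction. Voom weights gave 25 for SB939 against SAHA and 3518 for the interaction. With only the 4 compared libraries, limma gave 0 calls for SB939 against SAHA, where 2664 clusters had an unadjusted p under 0.05. In DAC this setting gave 1532 rises and 219 falls, against 1883 and 674 with all libraries. For the combination against SB939 it gave 5521 and 515, against 6998 and 1632. Left-out libraries gave 1307 to 2417 calls in DAC and 23 to 582 for SB939 against SAHA. Depth order as a replicate block raised the calls to 3528 in DAC (2550 shared with the fit without it), 16148 in SB939, 15153 in SAHA, 19782 in the combination and 7105 for the interaction, and ended no call of a named gene. The labels give every treatment 1 paired-end and 1 single-end library. The deeper libraries' deviations correlated at 0.1002 to 0.563 between treatments, but which library has which format is not given.

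Clusters not seen in DMSO numbered, with floors of 0.5 and 5 TPM, 1035 and 133 in DAC, 1392 and 114 in SB939 and 1407 and 145 in SAHA, and 1556 at 5 TPM in the combination. A DMSO limit of 0.1 TPM gave 1186 in SB939 and 1287 in SAHA, and left-out libraries gave 691 to 1468 in SB939 and 780.0 to 1500.0 in SAHA. Family A clusters past 4-fold numbered 283 and 35 in DAC, 575 and 134 in SB939 and 636 and 165 in SAHA with pseudocounts of 0.1 and 5, and 847 in the combination with 5. The correlation of SB939 and SAHA changes was 0.828 with separate DMSO libraries and 0.963 at 5 TPM or more. Of 22 camera calls with the preset correlation, 1 held with an estimated correlation, cancer-testis antigens in DAC.

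The methylation difference from DMSO was, with minimums of 1, 3 and 10 calls, as the mean per CpG, from smoothed values and on autosomes, -34.1, -34.2, -34.2, -34.3, -34.0 and -34.4 points in DAC. In the same order it was -7.45, -7.46, -7.57, -6.74, -6.67 and -7.51 in SB939, and -34.97, -35.04, -35.01, -35.03, -34.8 and -35.3 in the combination. CpGs called in SB939 numbered 60 at 10 points. With windows of 200 and 1000 bp and minimums of 1 and 10 calls, promoters differed by -20.1, -28.1, -21.2 and -28.6 in DAC and by -4.85, -6.20, -5.17 and -6.18 in SB939, and gene bodies by -39.5, -40.2, -39.97 and -39.9 in DAC and by -8.19, -8.32, -8.20 and -8.45 in SB939. Family A copies differed by -34.8 in DAC at 10 calls. Mean DMSO levels around clusters past 4-fold, with windows of 200 and 1000 bp, a minimum of 10 calls and pooled calls, were 83.3, 81.7, 83.6 and 82.3% for DAC. With windows of 200 and 1000 bp, minimums of 1 and 10 calls and pooled calls, they were 45.3, 52.1, 47.96, 51.1 and 33.998% for SB939, 38.8, 47.6, 42.1, 45.6 and 28.987% for SAHA, 60.3, 64.1, 61.9, 63.4 and 50.5% for the combination, and 29.2, 40.6, 33.978, 39.1 and 17.1% for clusters under 2-fold.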

Other observations

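The tests of CCAAT boxes, of LTR12 genes and of methylation in copies that fire with SB939 alone had their expected outcomes written before the results were seen; the clusters used by a single treatment were looked for after the main results were known.

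Markers of cell types that this lung line should not express moved in the combination and, in part, in single treatments. COL1A1, a fibrillar collagen, was listed at 0 in DMSO, held 1.61 TPM in SB939 and rose to 29.5 TPM with DAC+SB939, and THY1, a fibroblast surface marker, rose from a listed 0 to 6.93 TPM in DAC and 15.2 TPM in the combination. Of 2 fibroblast markers tested, 1 rose in DAC (2 adjusted over the list alone), 1 in SB939, 1 in SAHA and 2 in the combination. CGA, a trophoblast hormone subunit, rose from 0.0542 to 122 TPM in the combination (6.87 ± 0.19 SE), and both tested trophoblast markers rose in SB939, SAHA and the combination and neither in DAC. TYROBP, a leukocyte signalling adaptor, rose from a listed 0 to 2.60 TPM in DAC, and all 3 tested genes of the leukocyte list, which also holds the erythroid gene HBA1, rose in DAC and in the combination, 1 in SB939 and 1 in SAHA. Camera gave them an adjusted p = 9.7e-04 in DAC (adjusted p = 0.0874 with an estimated correlation). Of the 3 DAC calls 2, among them that of HBA1, ended without the deeper DMSO library, the shallower DMSO library or the shallower DAC library, and the SB939 call ended without the shallower DMSO library. CLDN5, an endothelial claudin, was listed at 0 in DMSO and held 2.31 TPM in the combination, where both tested endothelial markers rose, with 0 in DAC, 1 in SB939 and 1 in SAHA. The SB939 call, of ESAM, ended without the shallower DMSO (0.98) or the shallower SB939 library (0.81). FOXJ1, the 1 lung epithelial marker tested, rose from 0.0271 TPM in DMSO to 11.6 TPM in the combination (3.61 on the log2 scale) and passed limma's threshold in all 4 treatments. It did not without the deeper DMSO library (0.89 in SB939, 0.95 in SAHA), the shallower DMSO library (0.81, 0.87) or the shallower library of the compound (0.62, 0.84). Most list members were below detection, since 16 leukocyte, 10 fibroblast, 8 endothelial, 12 lung epithelial and 11 trophoblast genes had 3, 3, 2, 1 and 2 measured. A marker silent in DMSO was tested only where a treatment raised it, so the filter favoured rises among the tested markers.

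Control genes moved little in DAC, with none of 6 tested past limma's threshold, while 0 rose and 1 fell in SB939, 1 and 1 in SAHA and 1 and 2 in the combination. HPRT1, a purine salvage enzyme, fell from 102 to 47 TPM in SB939 (log2 change -1.10, adjusted p = 0.00039 with limma and Benjamini-Hochberg). Over the 12 control genes measured the median in the combination was 0.09, and -0.50 with the median of all clusters set to 0 and -0.08 with quantile normalization. The authors' means of B2M, a class I subunit, were 542 TPM in DMSO and 999.7 TPM in the combination, those of YWHAZ, an adaptor protein, 1073 and 603 TPM, and those of PEG10, a retrotransposon-derived imprinted gene, 164 TPM in DMSO and 1653 TPM in SB939, none of them tested.

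Some clusters were used by 1 treatment only, at 20 TPM or more there and under 1 TPM elsewhere. The combination had 305 of them, of which 303 held in both libraries, and SB939 and SAHA had 0. DMSO had 2, the YME1L1 cluster (chromosome 10, 27425251 to 27425295, minus strand) with 159.7 and 67.5 TPM in its libraries and a second on chromosome 9 with 91.9 and 74.8 TPM. DAC had 1, a 1-bp cluster in MAF1, a repressor of RNA polymerase III (chromosome 8, 145159652, plus strand), with 74.7 and 154 TPM in its libraries in sequence 1.31% methylated in DMSO.

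That family A belongs to the LTR12 class of ERV9 repeats was tested as a hypothesis. If it holds, genes reported to start in LTR12 should hold a sense copy in or within 10 kb upstream of the gene, and 5 of 7 did: ADH1C, GBP2, GBP5, TNFRSF10B and ZNF80, but not AXIN1 and TP63. Random sets of 7 protein-coding genes held 0.21 on average in 10000 draws, with a central 95% reaching up to 1.

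CCAAT boxes, which bind the factor NF-Y, might mark the family A copies that fire in the combination. Within 230 bp upstream they did not: firing copies held 2.81 boxes on average (1977 copies) and the others 2.95 (2002 copies). The difference was -0.136 ± 0.0328 SE (permutation test with 10000 draws, two-sided, p = 2.0e-04), opposite to the hypothesis. Copies share sequence and are not independent, so this SE and p-value may be too small. Only copies with at least 300 bp aligned to the seed were counted, and boxes further upstream were not. The share that fired had no steady trend, with 46.3% of 229 copies with 1 box, 58.1% of 1445 with 2, 42.4% of 1058 with 3, 46.3% of 1028 with 4 and 49.0% of 206 with 5.

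Lower methylation in DMSO might mark the copies that SB939 alone could switch on. Copies at 1 TPM or more in SB939 had a mean level of 75.4% (558 copies) and those that needed DAC 78.7% (1398 copies), a difference of 3.31 ± 1.06 SE percentage points. With 1 bisulfite library per treatment and both groups highly methylated, the data do not settle this.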
